A study of Mus musculus with 6 samples.

How the data were processed

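Epididymal white adipose tissue of mice was kept in RNAlater, total RNA was extracted with Trizol, and libraries were made with a stranded mRNA kit (TruSeq Stranded mRNA LT), per the labels' protocols. The labels give 3 libraries of the floxed Pak4 genotype (labelled WT) and 3 of the floxed genotype with Adipoq-Cre (labelled KO), all after 24 h of fasting. They name adipocytes as the cell type, while the protocol describes whole tissue. Each library was assigned to its group by its title. The submitters' processing notes name bcl2fastq 2.20.0, FastQC 0.11.7, HISAT2 2.1.0, Bowtie2 2.3.4.1 and StringTie 2.1.3b and the genome build mm10. They give no role or order for these tools. Whether the counting used strand and how reads that match several places were treated is not given in the sources used here, so genes that overlap on opposite strands and near-identical copies are uncertain.

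The authors deposited 1 table of 45777 genes with 3 units per library, named per the file headers. The deposited read counts are whole numbers per gene with no normalization, and they entered every test. The deposited FPKM values, scaled by the authors per kilobase of transcript and per 1000000 fragments, were used only to check the counts. The deposited TPM values, which sum to between 999992 and 1000000 per library, were used for the same check and for Pak4. No gene with a count of 0 had an FPKM above 0, and 2 to 6 genes per library had counts with an FPKM of 0. Symbols and identifiers are those of the table. Of the gene identifiers, 99.8% matched the RefSeq genes of GRCm38.p6, the assembly of mm10, from which coordinates were taken, and 98 did not match.

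Total counts were 63025412, 72005658 and 62854465 in the libraries labelled WT 1, 2 and 3, and 66881293, 65230001 and 70830615 in the libraries labelled KO 1, 2 and 3. Between 21749 and 22644 genes had a read in each library, and 26564 in any. The 10 most abundant genes took 15.4% to 16.3% of the counts. Mitochondrially encoded transcripts took 6.56% to 8.55%. No 2 libraries agreed within sampling noise, the lowest chi-square of a pair being 50.7 per degree of freedom, so all 6 were used as separate libraries. At these depths a gene at 1 CPM has more than 62 counts per library. The biological coefficient of variation, as the square root of the common dispersion, was 0.200.

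Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 17820. Counts were scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with a quasi-likelihood model (robust glmQLFit) on the label alone. The test (glmQLFTest) was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are those for which the squared ratio of fold change to error equals the test's F statistic. The log2 CPM values per library behind principal components and list scores used a prior count of 2. Exact permutation tests of 3 libraries against 3 cannot give a two-sided p under 0.1.

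The groups, tests, alternatives, gene lists and rule for named genes were fixed before the data were examined. The rule names Pak4, then up to 12 genes with the largest rise and up to 12 with the largest fall among those past the threshold whose groups do not overlap, with a mean of at least 1 CPM and a symbol that is not a predicted gene. Because fewer than 10 genes passed, it adds the 10 genes with the smallest p under the same exclusions, of which Col8a1 passed and the rest are stated as not passing. For each list it adds up to 4 measured members with the smallest p. Other members are named where they passed when adjusted over the list alone, while Mlxipl, Srebf1, Lep and Adipoq from their lists, Scd1 for its abundance, and Gm7049, Gm11868, Cyb5r4 and Nt5e for the map were named after their values were seen.

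There were 39 lists of genes. They covered lipolytic enzymes and lipid droplet proteins, lipolytic receptors and cAMP signalling, fatty acid oxidation, PPAR alpha targets, thermogenic genes, de novo lipogenesis, fatty acid uptake and triglyceride synthesis, insulin signalling, oxidative phosphorylation, mitochondrially encoded transcripts, branched-chain amino acid catabolism, cholesterol synthesis and NRF2 targets. They also covered glucocorticoid-responsive genes, the circadian clock, the unfolded protein response, hypoxia, autophagy and lysosome, ribosomal proteins, extracellular matrix, inflammatory cytokines, interferon-stimulated genes, immediate early and heat shock genes, CREB targets, the cell cycle, PAK family effectors and the neighbours of Adipoq. Marker lists described mature adipocytes, macrophages, T and NK cells, B and plasma cells, neutrophils, endothelium, progenitors and fibroblasts, mesothelium, smooth muscle and pericytes, epididymal epithelium and sperm, skeletal muscle and erythroid cells. Lists with at least 5 measured members, 38 in all, were tested with camera (limma 3.58.1) on voom-weighted values with a preset correlation of 0.01. The same lists were tested with an estimated correlation, under which 0 of 38 passed. They were also tested with fry, which asks whether a list's genes move on balance one way without comparing them with other genes; 0 passed that test, and 17 passed its test for change in either direction.

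Alternatives were RLE scaling, library size alone, no filter, a stricter filter (at least 1 CPM in 3 libraries), DESeq2 1.42.0, limma voom, an adjusted p under 0.1, a fold of at least 2, each library left out in turn, and the replicate number as a block. An edgeR fit with robust dispersion was added after seeing the data. DESeq2 left 30121 adjusted p as NA, and these were kept out of all counts. Counts simulated from these libraries' means, sizes and dispersions for the comparison of KO with WT labels, with 50 genes changed at each fold among 17481 tested, were used as a check. The edgeR fit recovered 22% of genes changed 1.5-fold, 74% at 2-fold, 92% at 4-fold and 98% at 8-fold, and 15 of its 158 calls were false. With 5 of 38 lists raised by 0.5 on the log2 scale, camera recovered 5 and also called 2 unchanged lists. Each gene was simulated independently of the others, so this check does not cover lists whose genes are correlated. All libraries of a label were drawn from the same mean per gene, so a library that lies apart from its group is not covered either. The shares recovered therefore need not hold for the real libraries, where Fasn (4.03-fold) and Pcdhga9 (7.44-fold) did not pass.

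Pseudogenes among the tested genes were aligned to the protein-coding transcripts of GENCODE M21 (GRCm38) with BLAST 2.17.0. Of 1116 pseudogenes, 913 had a sequence there, and 873 of them matched a protein-coding transcript at 90% identity or more over at least 200 bases. The best match is called the parent, which was itself tested for 859. Matches of a gene to its own symbol were not removed, as for Cd1d2, and such pairs differ by 0 in the comparison with parents below. Transcript length and GC content were taken from the longest GENCODE transcript of each gene, which 92.4% of tested genes and all members of the lists that passed had. Figures were drawn with matplotlib 3.10.9.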

Results

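Gene expression was measured by mRNA sequencing of epididymal white adipose tissue, the fat pad next to the epididymis, from mice fasted for 24 h on a C57BL/6 background. There were 6 libraries in 2 groups of 3. By the labels, the WT libraries came from mice with loxP-flanked (floxed) alleles of Pak4. Pak4 is a serine/threonine kinase activated by small GTPases of the CDC42 family. The libraries labelled KO are described as coming from floxed mice that also carried Adipoq-Cre, which expresses the Cre recombinase in adipocytes. The comparison asks how loss of Pak4 from adipocytes alters the transcripts of the fasted fat pad. Total counts ran from 62854465 to 72005658 per library, and Scd1, a fatty acid desaturase, was the most abundant gene in all 6, with 2.83% to 4.50% of the counts. The labels number the replicates of each group without saying that each number is a separate mouse, so p-values measure the spread between these libraries. All values below are TMM-scaled CPM (counts per 1000000 counts of a library) as mean ± SD with n = 3 per group unless stated, and all fold changes are log2 values of the libraries labelled KO over the libraries labelled WT, ± SE.

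Pak4, the targeted gene, was not lower in the libraries labelled KO. It had 339, 337 and 358 counts in the libraries labelled WT and 815, 744 and 675 counts in the libraries labelled KO. The means were 5.47 ± 0.41 CPM and 10.6 ± 1.53 CPM, a log2 fold change of 0.96 ± 0.14, with all 3 libraries labelled KO above all 3 labelled WT. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment the adjusted p was 0.0898, short of the threshold of 0.05. The authors' deposited TPM of Pak4 had the same order, at 3.49, 3.04 and 3.82 in the libraries labelled WT and 7.85, 7.26 and 5.85 in those labelled KO. Exact binomial 95% intervals of its unscaled CPM reached at most 6.32 in a library labelled WT and started at 8.82 or more in the libraries labelled KO; such intervals cover counting error only, because PCR copies of one molecule are counted as separate reads. Pak4 is a protein-coding gene on chromosome 7, 28558819 to 28598184 in mm10, and the values are totals per gene, so reads from the floxed exons cannot be separated from the rest. Because the targeted gene goes against the labels, every direction below is given between libraries by their labels and not between genotypes. The call depended on the test and on 1 library: Pak4 passed with DESeq2 (log2 fold change 0.95, adjusted p 1.72e-05) and in edgeR without the library labelled KO 1 (0.85, adjusted p 0.0313), and its adjusted p ranged from 1.72e-05 to 0.403 over all alternatives.

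**Figure D1:**
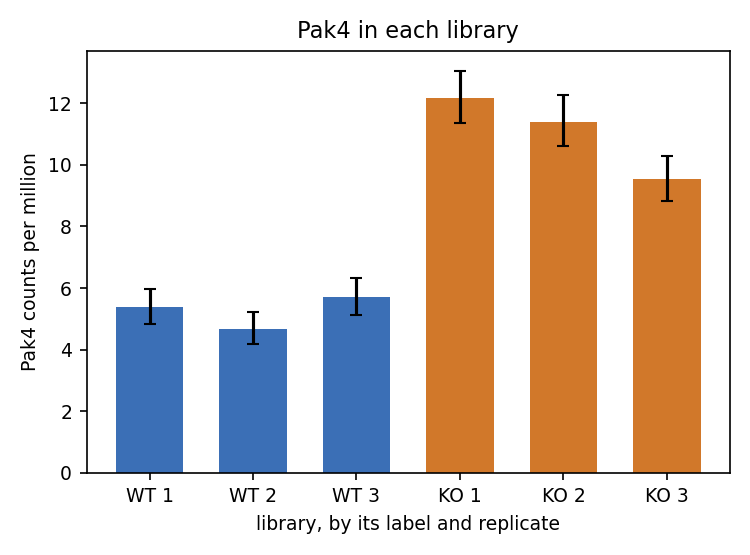
Unscaled CPM of Pak4 in each library (bars) with exact binomial 95% intervals (lines). The 3 libraries labelled WT hold 4.68 to 5.70 CPM and the 3 labelled KO hold 9.53 to 12.2.

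Col8a1 and 2 pseudogenes were the genes that passed the threshold in edgeR's test, and all 3 were lower in the libraries labelled KO. Col8a1, which encodes a short-chain collagen of vessel walls, fell from 31.8 ± 2.54 to 10.6 ± 1.24 CPM (log2 fold change -1.58 ± 0.12, adjusted p 0.00751 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; chromosome 16, 57624256 to 57754737). Gm7049, a pseudogene on chromosome 13 at 62812916 to 62815515, fell from 20.1 ± 1.15 to 1.91 ± 0.32 CPM (-3.40 ± 0.15, adjusted p 3.73e-04 in the same edgeR test). Gm11868, a pseudogene on chromosome 4 at 18844005 to 18845867, fell from 3.02 ± 0.44 to 0.15 ± 0.05 CPM (-4.34 ± 0.30, adjusted p 0.00619 in edgeR). Both pseudogenes fall outside the rule for named genes and are named because the count is small, after their values were seen. Gm7049 is 98.4% identical to Me1 over 1716 bases and Gm11868 is 98.0% identical to Cyb5r4 over 1485 bases, so their counts can hold reads of those genes and are uncertain. Me1, which makes NADPH from malate, had a log2 fold change of -0.51 ± 0.12 and Cyb5r4, a cytochrome b5 reductase, one of 0.18 ± 0.10.

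**Figure D2:**
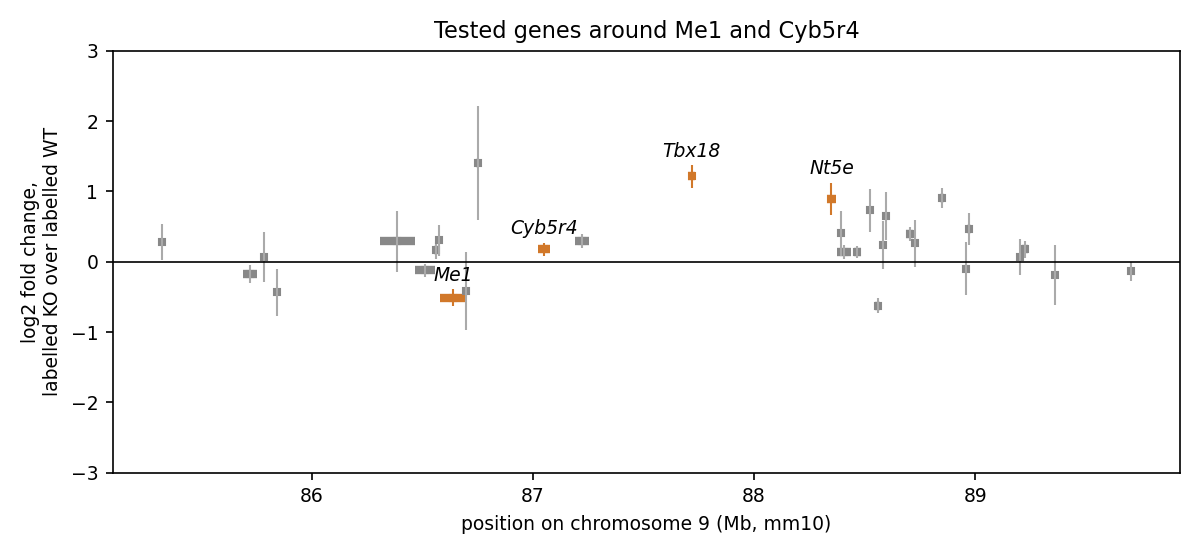
Log2 fold changes (y axis, libraries labelled KO over labelled WT, lines give ± SE) of tested genes by position on chromosome 9 in Mb of mm10 (x axis), around Me1 and Cyb5r4, the genes that the pseudogenes resemble. Me1 stands at -0.51 and Cyb5r4 at 0.18, while Tbx18 and Nt5e stand at 1.21 and 0.90; none of the 4 passed the test.

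In all, 3 of 17820 tested genes passed, 0 higher and 3 lower in the libraries labelled KO, by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 1721 higher and 1730 lower genes, against 891 in all from chance and 197 to 2312 in the other splits of the 6 libraries, the highest with WT 1 and KO 1 exchanged, and 26.2% of genes had groups that did not overlap, against 10% from chance. DESeq2 called 416 genes higher and 620 lower, limma voom 1 higher and 4 lower, and scaling by library size alone 1 higher and 3 lower in edgeR. The count also turned on single libraries: it was 1016 without the library labelled KO 1, 5 without WT 1, and 1 without WT 2, WT 3 or KO 3. KO 1 lay at -1.85 on the first principal component (44.1% of the variance), between the libraries labelled WT (-12.3, -53.5 and -26.7) and those labelled KO 2 (40.9) and KO 3 (53.5). Col8a1 missed the threshold when WT 2, WT 3, KO 2 or KO 3 was left out and Gm11868 when WT 2, WT 3 or KO 3 was, with adjusted p up to 0.0967 and 0.0772 in edgeR, while Gm7049 passed in all 16 alternatives.

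The 9 genes other than Col8a1 with the smallest p in the rule for named genes did not pass. Eln, which encodes elastin, had 209 ± 30.1 and 103 ± 10.8 CPM in the libraries labelled WT and KO (log2 fold change -1.03 ± 0.13). Aqp1, a water channel of endothelium and other cells, had 91.9 ± 3.09 and 53.1 ± 3.50 CPM (-0.79 ± 0.09). Ramp2, a partner of the adrenomedullin receptor, stood at -0.66 ± 0.09, and Hmcn2, a matrix protein of the hemicentin family, at -0.68 ± 0.09. Odf3l1 stood at -1.71 ± 0.23. On the other side, the transcription factor genes Tbx18 (1.21 ± 0.16), Nr2f2 (0.82 ± 0.11) and Bhlhe40 (0.81 ± 0.09) had more counts in the libraries labelled KO. Pcdhga9 stood at 2.90 ± 0.32, with 0.76 ± 0.28 and 5.67 ± 1.33 CPM. It shares its last exons with the other gamma protocadherins, of which 21 were tested, with log2 fold changes of -0.54 to 0.71, so its counts are uncertain. The adjusted p of these 9 genes lay between 0.0810 and 0.0877 in edgeR's quasi-likelihood test, and all 9 passed with DESeq2 and in edgeR without the library labelled KO 1. Pcdhga9 alone among them also passed in edgeR with scaling by library size alone or without the filter on low counts.

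**Figure D3:**
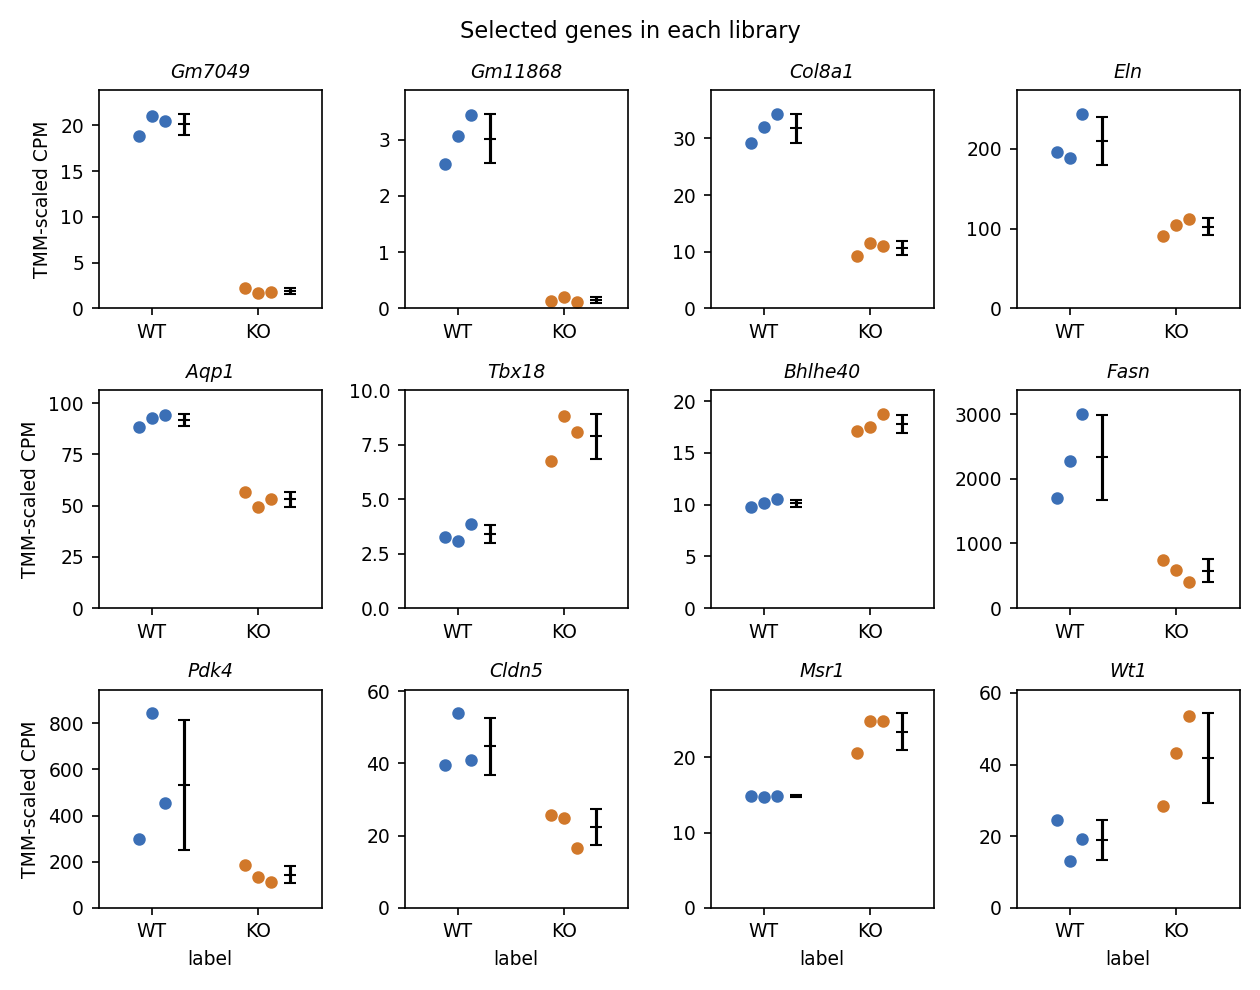
TMM-scaled CPM of 12 genes in each library (points), by label, with mean ± SD (n = 3) beside them. Gm7049, Gm11868 and Col8a1 passed the test; Eln, Aqp1, Tbx18, Bhlhe40, Fasn, Pdk4, Cldn5, Msr1 and Wt1 are shown as values that did not pass when adjusted over all genes.

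The list of fatty acid synthesis genes passed camera towards lower values in the libraries labelled KO. Fasn, the fatty acid synthase, had 2331 ± 655 CPM in the libraries labelled WT and 578 ± 177 CPM in those labelled KO (log2 fold change -2.01 ± 0.29). Elovl6, an elongase, stood at -1.22 ± 0.26, Acss2, which makes acetyl-CoA from acetate, at -0.82 ± 0.18, and Slc25a1, the mitochondrial citrate carrier, at -0.70 ± 0.11. Of 17 measured genes of de novo lipogenesis, 0 passed over all genes, while 8 fell and 0 rose when adjusted over the list alone (Acaca, Fasn, Scd2, Elovl6, Me1, Pnpla3, Slc25a1 and Acss2). The list had a median log2 fold change of -0.45 and passed camera, a test of a list against all other genes, with an adjusted p of 5.90e-04. The call was lost at adjusted p = 0.517 with an estimated correlation. With the preset correlation, camera called 15 lists for the labels and 5 to 12 in each other split of the 6 libraries. Mlxipl and Srebf1, which encode transcription factors of lipogenesis, stood at 0.08 ± 0.17 and 0.15 ± 0.18.

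Lists of lipolytic enzymes, lipolytic receptors and fatty acid uptake also passed camera towards lower values in the libraries labelled KO, with members on both sides of 0. Lpl, the lipoprotein lipase, had 13049 ± 363 and 8787 ± 1278 CPM (-0.57 ± 0.17), and Pnpla2, the adipose triglyceride lipase, 3969 ± 226 and 2838 ± 204 CPM (-0.48 ± 0.14). Among 16 lipolytic enzymes and lipid droplet proteins (median -0.32), Pnpla2 and Fabp5 fell and Ces1d, a carboxylesterase, rose when adjusted over the list alone. Of 19 genes of lipolytic receptors and cAMP signalling (median -0.25), 4 fell and 1 rose when adjusted over the list alone. Those that fell included Npr3, the natriuretic peptide clearance receptor (-1.48 ± 0.37), and Prkar2b, a regulatory subunit of protein kinase A (-0.78 ± 0.14), and the one that rose was Npr1, the natriuretic peptide receptor that makes cGMP (0.54 ± 0.15). Among 16 genes of fatty acid uptake and triglyceride synthesis (median -0.28) 0 passed when adjusted over the list alone. The camera adjusted p of these lists was 0.0265, 0.0153 and 0.0162 in this order, each lost at adjusted p = 0.517 with an estimated correlation. Camera also lost the lipolytic enzymes without WT 2 (adjusted p 0.0764) or KO 2 (0.0601), and the receptors (0.130) and uptake genes (0.127) without WT 1. The mean log2 CPM over the lipolytic enzymes and over the receptors overlapped between labels.

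Lists of fatty acid oxidation, oxidative phosphorylation, PPAR alpha targets and glucocorticoid-responsive genes passed camera towards lower values as well. Pdk4, a member of the last 2 lists, which restrains pyruvate oxidation in fasting, had 531 ± 281 and 144 ± 37.6 CPM (-1.88 ± 0.40), and Cpt1a, which admits fatty acids to mitochondria, 137 ± 13.8 and 103 ± 8.49 CPM (-0.42 ± 0.11). Of 20 fatty acid oxidation genes (median -0.16), Cpt1a, Acadl and Hsd17b4 fell when adjusted over the list alone, and of 25 oxidative phosphorylation subunits (median -0.17) none did, with 22 of 25 below 0. Among 16 PPAR alpha target genes (median -0.35), 5 fell when adjusted over the list alone (Pdk4, Angptl4, Vnn1, Acaa1b and Cpt1a). Among 17 glucocorticoid-responsive genes (median -0.44), 4 did (Pdk4, Angptl4, Zbtb16 and Ddit4), so Pdk4 and Angptl4 count in both. Camera gave adjusted p of 0.00227, 9.45e-04, 0.0329 and 0.0265 for these lists in this order, each lost at adjusted p = 0.517 with an estimated correlation. PPAR alpha targets lost the camera call without WT 2 (0.0548), WT 3 (0.139) or KO 2 (0.0912), and glucocorticoid-responsive genes without WT 1 (0.0743), WT 2 (0.0548), KO 1 (0.197) or KO 2 (0.0529). The mean log2 CPM over each of these lists, PPAR alpha targets and glucocorticoid-responsive genes, overlapped between labels.

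Matrix and endothelial lists passed camera towards lower values in the libraries labelled KO. Col6a1, a chain of collagen VI, had 773 ± 178 and 376 ± 54.3 CPM (-1.04 ± 0.19), and Ccn2, the connective tissue growth factor, stood at -1.30 ± 0.24. Of 21 extracellular matrix and fibrosis genes (median -0.53), 9 fell and 1 rose when adjusted over the list alone, with 0 passing over all genes. Cldn5, a tight junction protein of endothelium, had 44.8 ± 7.89 and 22.4 ± 5.05 CPM (-1.00 ± 0.19), and Cdh5, the cadherin of endothelium, 46.3 ± 9.09 and 28.2 ± 3.29 CPM (-0.71 ± 0.16). Of 16 endothelial markers (median -0.39), 5 fell when adjusted over the list alone (Cdh5, Tie1, Kdr, Robo4 and Cldn5). Camera gave adjusted p of 7.69e-04 for the matrix list and 1.73e-04 for the endothelial list, each lost at adjusted p = 0.517 with an estimated correlation. Smooth muscle and pericyte markers did not pass camera (adjusted p 0.0569), while Rgs5, Notch3 and Mylk fell and Smtn rose when adjusted over the list alone.

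Macrophage, mesothelial, B cell and interferon-stimulated genes passed camera towards the libraries labelled KO, although single libraries overlapped. The scavenger receptor gene Msr1 had 14.8 ± 0.12 and 23.4 ± 2.42 CPM (0.66 ± 0.10), and Trem2, a receptor of lipid-laden macrophages, 13.9 ± 2.57 and 28.0 ± 8.03 CPM (1.01 ± 0.24). Of 20 macrophage markers (median 0.26), Mrc1, Trem2, Msr1 and Clec10a rose when adjusted over the list alone. Wt1, a transcription factor of mesothelium, the cell layer that covers the fat pad, had 18.9 ± 5.69 and 41.8 ± 12.5 CPM (1.14 ± 0.29), in a list of 14 (median 0.53) with 0 passing alone and 13 above 0. Mzb1, a plasma cell gene (1.43 ± 0.33), rose when adjusted over the list alone of 14 B cell and plasma cell markers (median 0.49), as did Cmpk2 (0.66 ± 0.15) among 19 interferon-stimulated genes (median 0.33). Camera gave adjusted p of 1.73e-04 for macrophage markers, 1.73e-04 for mesothelial markers, 0.00335 for B and plasma cell markers and 0.00142 for interferon-stimulated genes. Each was lost at adjusted p = 0.517 with an estimated correlation. The mean log2 CPM over the list overlapped between labels for all 4: WT 1 lay above KO 1 for mesothelial (5.85 and 5.80), interferon-stimulated (3.60 and 3.51) and B cell and plasma cell genes (1.61 and 1.23), and WT 2 above KO 1 for macrophage markers (5.98 and 5.97). With 1 library left out, the camera adjusted p of B and plasma cell markers ran from 3.21e-06 without WT 1 to 0.0360 without WT 2.

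All 20 measured cytosolic ribosomal protein genes lay above 0, with a median log2 fold change of 0.23 and 0.39 ± 0.13 for Rpl3. The list rose by camera (adjusted p 1.70e-04; adjusted p = 0.517 with an estimated correlation), and 0 of its members passed when adjusted over the list alone. Scaling by library size alone moved the median of all genes by 0.12 on the log2 scale, and no median of the 15 lists that passed camera changed sign under it or under the RLE scaling. TMM factors were 0.931 to 0.976 in the libraries labelled WT and 1.01 to 1.07 in those labelled KO. With library size alone the medians of fatty acid oxidation and oxidative phosphorylation shrank to -0.04 and -0.05, while 0 lists lost their camera call.

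**Figure D4:**
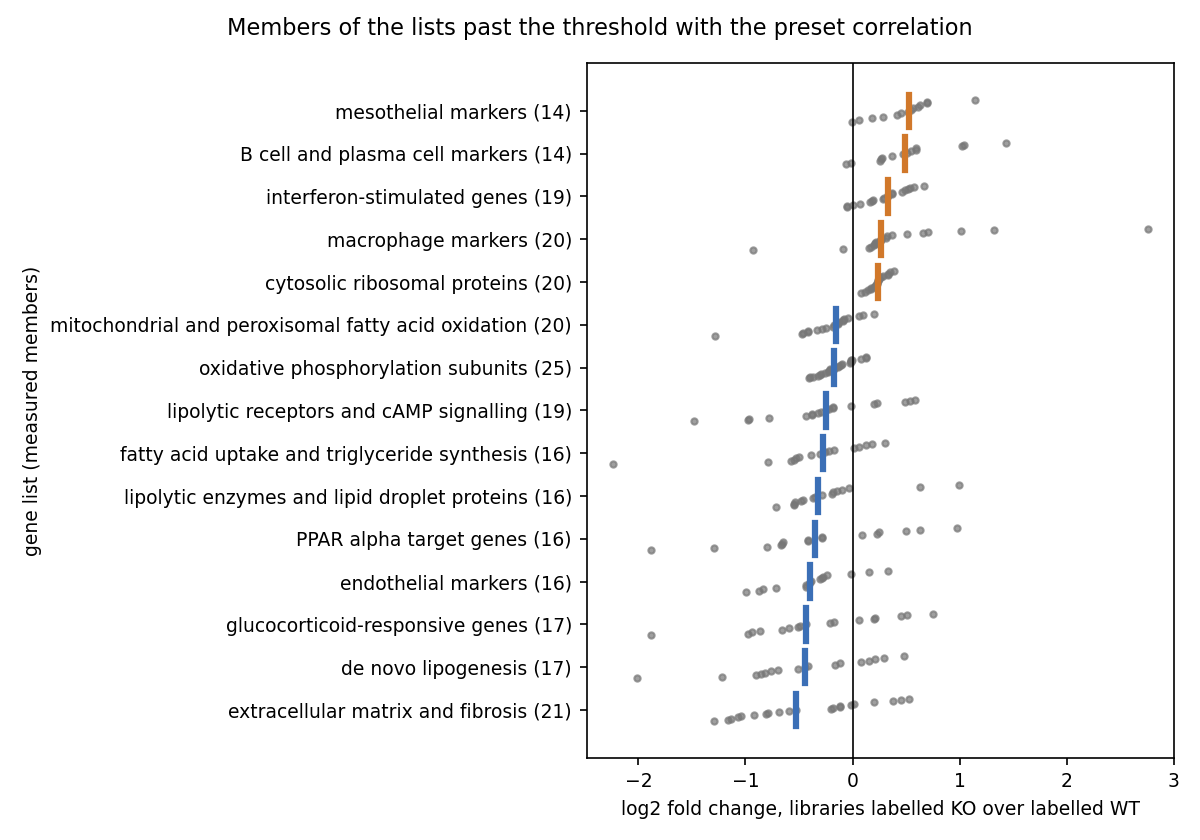
Log2 fold changes (x axis, libraries labelled KO over labelled WT) of the measured members (grey points) of the 15 gene lists that passed camera with the preset correlation, with the median of each list as a coloured bar. Medians run from -0.53 for extracellular matrix and fibrosis to 0.53 for mesothelial markers.

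Circadian clock genes went both ways. Bhlhe40 (0.81 ± 0.09), Bhlhe41 (1.01 ± 0.15), Nr1d1 (0.98 ± 0.18) and Ciart (1.43 ± 0.43) rose and Cry1 (-0.61 ± 0.13) fell when adjusted over the list alone, with 0 of 18 passing over all genes and a camera adjusted p of 0.0978. The clock list passed fry for change in either direction (adjusted p 7.99e-04), 1 of 17 lists among 38 that did. Its mean log2 CPM was 3.89 ± 0.20 and 4.24 ± 0.14 (SD), higher in every library labelled KO than in any labelled WT. Adipocyte identity genes did not move as one group. Of 18 mature adipocyte markers, Pparg (0.61 ± 0.14) rose when adjusted over the list alone, Cfd, which encodes adipsin, stood at 1.02 ± 0.32 and Lep, which encodes leptin, at -1.14 ± 0.49, and the camera adjusted p was 0.347. Thermogenic adipocyte genes (camera adjusted p 0.111) had 0 members past the threshold when adjusted over the list alone. Cholesterol synthesis genes (0.278) included Nsdhl (-0.83 ± 0.16), lower when adjusted over the list alone, and NRF2 targets (0.280) had Me1 and Taldo1 (-0.43 ± 0.11) lower. Of 7 measured neutrophil markers (0.149), S100a8 (-1.60 ± 0.40) fell and Mmp9 (1.00 ± 0.30) and Csf3r (0.53 ± 0.19) rose when adjusted over the list alone.

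Members that passed only when adjusted over the list alone were also Pak6 (2.39 ± 0.54, at 0.11 ± 0.06 and 0.58 ± 0.25 CPM) in the PAK family and small GTPase effectors, Actn3 (1.19 ± 0.28) in the skeletal muscle markers, Hsph1 (-0.61 ± 0.12) in the immediate early and heat shock genes, and Pde4d (-0.97 ± 0.19) in the CREB targets. Camera gave adjusted p of 0.823, 0.572, 0.976 and 0.0911 for these lists. Rfc4 (-0.43 ± 0.14), Masp1 (-0.61 ± 0.17) and Dnajb11 (-0.33 ± 0.10) fell when adjusted over the list alone of 10 measured neighbours of Adipoq on chromosome 16 (camera adjusted p 0.247), and Adipoq itself stood at 0.25 ± 0.18. Lists with 0 members past the threshold either way were insulin signalling (camera adjusted p 0.345), mitochondrially encoded transcripts (0.298), branched-chain amino acid catabolism (0.823), unfolded protein and integrated stress response (0.345), hypoxia-responsive genes (0.345) and autophagy and lysosome (0.0569). The same held for inflammatory cytokines and chemokines (0.247), T and NK cell markers (0.944), progenitor and fibroblast markers (0.447), erythroid markers (0.205) and cell cycle genes (0.692). Epididymal epithelium and sperm markers had 1 measured member, Rnase10, with 0.05 ± 0.09 and 0.15 ± 0.01 CPM, and were not tested.

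For these 23 lists that camera did not call, medians ran from -0.31 to 0.45, and 10 of the medians changed sign under another scaling. With 1 library left out, camera called autophagy and lysosome in 3 of 6 fits, and smooth muscle and pericyte markers and CREB targets in 2 each. Circadian clock, mitochondrially encoded and cell cycle genes were each called in 1. Median and mean differed in sign for NRF2 targets (0.01 and -0.12), hypoxia-responsive genes (-0.09 and 0.00), PAK family and small GTPase effectors (-0.03 and 0.12) and skeletal muscle markers (0.00 and -0.23), and camera put immediate early genes on the lower side with a median and mean of 0.01. No member of any list passed when adjusted over all genes in edgeR's quasi-likelihood test. With DESeq2, 84 of the 156 named genes other than Pak4 passed over all genes. Counted over whole lists, DESeq2 called 8 de novo lipogenesis genes lower, 9 matrix genes lower and 1 higher, 5 endothelial markers lower and 4 macrophage markers higher.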

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

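The robust dispersion alternative and the splits of the libraries were chosen only after the results were seen. The main count was 3 genes past the threshold, 0 higher and 3 lower in the libraries labelled KO. It was also found with RLE scaling, the stricter filter, a fold of at least 2 and robust dispersion. It became 1036 (416 higher, 620 lower) with DESeq2, 5 with limma voom (1 higher), 47 (17 higher, 30 lower) at an adjusted p under 0.1, and 4 with library size alone or without a filter (1 higher each). Leaving out each library in turn gave 1 to 1016 genes, 0 to 379 higher and 1 to 637 lower, with the high end without KO 1; of those 1016 genes, 565 were among the 1036 of DESeq2. The cause was not tested. The Pak4 log2 fold change kept its direction, at 0.95 with DESeq2 and 0.96 at an adjusted p under 0.1, where it passed, and at 0.85 to 1.06 with libraries left out, where it passed without KO 1. The replicate block gave 1 gene past the threshold (0 higher, 1 lower), 17 lists and a Pak4 log2 fold change of 0.95. It lost Col8a1 (adjusted p 0.0606) and Gm11868 (0.0835) in edgeR's quasi-likelihood test. Deviations of same-numbered libraries from their group means correlated at -0.17, -0.02 and 0.05, and not every library correlated best with its own number. Such deviations sum to 0 within each group of 3, so these values cannot decide whether the numbers pair the libraries. Of 38 tested lists, 15 passed camera and 12 to 18 did with libraries left out, other scalings or filters, while 0 passed with an estimated correlation or with fry. For 156 named genes and both pseudogenes, 2510 comparisons with an alternative gave 2349 on the same side of the threshold, 152 newly past it and 9 no longer past it, and 493 for lists gave 435, 17 and 41; none turned direction past the threshold. With 3 libraries against 3 the 10 splits are too few for a share under 0.05. The real split, 1 of the 10, gave 3 genes and 15 lists. Each other split gave 0 genes and 5 to 12 lists, so camera with the preset correlation called lists under every split of these libraries. At these depths, 62854465 counts or more, 22% of simulated 1.5-fold changes were recovered, a share that need not hold for the real libraries. Depth and spread were not varied, so what each limits was not separated.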

Other observations

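The tests of explanations below were chosen only after the results were seen, apart from the list of genes next to Adipoq, which was fixed beforehand. Some genes had reads in every library of 1 label and almost none under the other. With at most 3 counts summed over a group and at least 5 in every library of the other, 26 genes were seen in the libraries labelled KO and 17 in the libraries labelled WT, among 26564 genes with a read in any. These genes were not counted for other splits of the libraries, so whether the labels give more of them than another split was not tested. Mapk10, which encodes a Jun N-terminal kinase, had 27, 23 and 42 counts in the libraries labelled KO and 0 in each labelled WT, at least 29.9-fold higher against a floor of 3 counts over the group (adjusted p 0.0898 in edgeR's quasi-likelihood test). Snap91, which encodes a clathrin assembly protein, had 5, 11 and 11 counts in the libraries labelled WT and 0 in each labelled KO, at least 9.23-fold higher in the former, and was too low to be tested. Snap91 (chromosome 9, 86765923 to 86880734 in mm10) lies between Me1 and Cyb5r4, the genes that the 2 pseudogenes resemble. These genes were named after their values were seen.

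Pak4 lay higher in all 3 libraries labelled KO than in all 3 labelled WT. More cells of all types other than adipocytes would leave the macrophage minus endothelial marker score (mean log2 CPM) unchanged. That score was 1.55 ± 0.08 and 2.37 ± 0.36 (SD, n = 3) in the libraries labelled WT and KO, a difference of 0.82 (exact permutation p 0.1, the smallest possible). Both lists were picked after camera had called them in opposite directions, so the score is no independent test. It concerns a uniform mixture only, and a rise of single cell types that hold Pak4 was not tested. An exchange of the labels of both groups cannot be told apart from correct labels here: genes next to Adipoq, which the Cre transgene could carry as extra copies, did not pass camera (adjusted p 0.247), no count of Cre was at hand, and counts per gene do not resolve the floxed exons. Those 10 genes went both ways and passed fry for change in either direction (adjusted p 7.99e-04), 1 of 17 lists among 38 that did. Of the 10, 6 stood lower in the libraries labelled KO, with Rfc4, Masp1 and Dnajb11 past the threshold over the list alone. The other 4 stood higher, and Fetub (1.83) and Tbccd1 (0.11) were higher in every library labelled KO than in any labelled WT. Fetub is near the floor, at 0.14 ± 0.13 and 0.52 ± 0.18 CPM in the libraries labelled WT and KO. A transcript kept by the recombined allele, or more Pak4 in cells without Cre, also stays open and was not tested.

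Gm7049 and Gm11868 fell far more than the genes they resemble. A change of the parents themselves is argued against, since Me1 stood at -0.51 and Cyb5r4 at 0.18, and both pseudogenes differed from their parents by -2.88 and -4.52. These were the 2 largest differences among 859 pseudogenes with a tested parent (SD 0.33). Both were picked for passing the test, so their rank is no independent support. The SD is lowered by near-identical copies, such as Gm12671 of Gapdh with a difference of -0.02. The parents lie 0.44 Mb apart on chromosome 9, as near as 0.122% of 116403 pairs of such parents, so a candidate explanation is a stretch of that chromosome that differs from the reference genome in the libraries labelled WT, with its reads assigned to the pseudogenes. The reverse, a stretch in 1 copy in the libraries labelled KO that takes matches away, is argued against because losing 1 of 2 copies could at most double the ratio, while Gm7049 was 10.5-fold and Gm11868 20.3-fold higher in the libraries labelled WT. Whether such a stretch goes with the Cre transgene, which would place Cre in the libraries labelled WT and turn every direction between genotypes, or was carried by 2 copies in the libraries labelled KO, stays open without reads.

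The lists that passed camera moved in opposite directions. A lower share of adipocytes that raises all other cell types alike had no independent test. The macrophage minus endothelial score, 0.82 higher in the libraries labelled KO, was taken from 2 lists already seen to move apart. A shift alike in all these cell types would not by itself lower endothelial markers, while shifts that differ between cell types stay open. Transcript length and GC content are argued against as the whole cause. This check used a form of camera on signed z values from edgeR's p, not on voom values. With the preset correlation 15 of the 15 lists passed it before a fit on both and 15 after. The matrix median moved from -0.53 to -0.41. Smooth muscle and pericyte markers, outside the 15, went from an adjusted p of 0.0398 to 0.0754 in this form of camera. A change in the share of macrophages, mesothelium or endothelium alone also had no independent test. Genes of de novo lipogenesis are markers of none of these. Their mean log2 CPM was 7.60 ± 0.08 and 7.14 ± 0.11 (SD) in the libraries labelled WT and KO, without overlap. This list was picked after camera had called it, and more counts from other cells would lower adipocyte genes in CPM. The same score over mature adipocyte markers overlapped, with a difference of -0.09 against -0.46 for de novo lipogenesis. Effects of these cells on others, and the genotype itself, stay open as untested, and with an estimated correlation 0 lists passed.

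Near Me1 and Cyb5r4, the genes Tbx18 (chromosome 9, 87702800 to 87731260) and Nt5e (88327609 to 88372089) stood at log2 fold changes of 1.21 ± 0.16 and 0.90 ± 0.23. In the 3 Mb from 86000001 to 89000000 on chromosome 9, picked as the richest of the windows that hold Tbx18, 6 of 23 tested genes had an unadjusted p under 0.01, against 5.91% of all genes, and 79.0% of 1000 shuffles of the genes held a window somewhere at least as rich. Of 4 other pseudogenes whose parents lie within 5 Mb, all copies of Morf4l1, Morf4l1-ps1 stood at -0.58 (unadjusted p 4.88e-04), a difference of -0.72 from Morf4l1. Gm5539, Gm4835 and Gm5564 stood at 0.21, 0.12 and 0.01 (unadjusted p 0.322, 0.806 and 0.945).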
